A study of Homo sapiens with 6 samples.

How the data were processed

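The series measured SOX9, a transcription factor of pancreatic progenitor and duct cells, in PANC-1, an established line from a human pancreatic ductal adenocarcinoma. Per the labels' protocols, cells were transfected with 25 nM of SOX9 siRNA or of control siRNA with Lipofectamine. They were pooled and harvested after 48 hours, with 2 libraries per siRNA. Total RNA was made into stranded libraries, which were sequenced as 100 bp read pairs to at least 60000000 reads each. Nothing in the labels says that the 2 libraries of a group came from separate cultures started on different days. The authors' p-values per gene therefore measure the spread between these libraries, which may be technical. The 2 SOX9 ChIP-seq samples were not analysed here.

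The submitters' processing notes name HISAT2 2.0.5, featureCounts and DESeq2 1.18.1 for the RNA libraries, without settings. The notes list the builds hg19 and mm10 with no role, and the gene symbols used here are human. Whether reads were counted by strand is not given in the sources used here, so overlapping and antisense genes are uncertain. The file used is the authors' DESeq2 comparison, per the file headers, with 1 row for each of 19830 genes. It has no values per library, so no standard deviation or test of single libraries could be made from it. Per the file headers, the authors' mean normalized count is a signal averaged over the libraries after scaling by size factors. The log2 fold change and its standard error are the authors' log2 values, and the Wald statistic is the authors' score. The p-value and adjusted p-value are the authors' as deposited.

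The authors' adjusted p-value is given for 14063 genes, called tested here. The other 5767 genes had mean normalized counts of 21.93 or less and were not tested. Taking Benjamini-Hochberg over the tested genes gave the deposited adjusted values to within 9.4e-15. The sum of mean normalized counts was 47653185, and the depth of single libraries is not in this table. The lowest mean counts are those of genes with few reads, and their steps gave relative size factors from 0.908 to 1.131, a ratio of 1.25.

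The headers do not state which group is the numerator. Fold changes are read as SOX9 siRNA relative to control siRNA because SOX9, the siRNA target, had a negative value. SOX9 therefore cannot serve as a check of the labels, and every direction given here would turn if the reading were wrong.

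Of the designs set before the data were examined, the branch for a file with only the authors' comparison was used. A gene was called at an adjusted p under 0.05. Intervals are 95% Wald intervals, 1.96 standard errors each way. Current symbols were looked up in a RefSeq gene table, which was used for names, gene order and genomic span. It held 19211 of the symbols, 1275 of them as older names, and 619 were not found.

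A total of 36 gene lists were fixed before the data were examined. The primary lists were pancreatic cancer biomarkers, intraflagellar transport, BBSome with transition zone and ciliary membrane, motile cilia, the Hedgehog pathway, and pancreatic duct and progenitor genes. The primary lists followed the series title, which names cancer biomarker genes and cilia genes. They were therefore not chosen blind to the submitters' account of these data. The other lists covered signalling, cell cycle, stress, differentiation, other cell types and technical classes. Of 1173 list entries, 1092 were matched to the table. Lists with at least 3 tested members were compared with all other tested genes by cameraPR of limma 3.58.1, two-sided, on the authors' Wald statistic. The preset inter-gene correlation was 0.01, and p-values were adjusted over 34 lists. Called and uncalled members were also compared by Fisher's exact test. Genes are the units in both tests and are not independent replicates, so the p-values do not measure the spread between libraries. The motile list was compared with the lists of primary cilia genes by a two-sided permutation test over genes with 100000 resamples, in which genes are not independent replicates.

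Genes were named by a rule set before the data were examined. SOX9 was always named. Among called genes with a mean normalized count of at least 100 and an ordinary symbol, the 8 largest rises and 8 largest falls were named. Each primary list added up to 4 called members with the smallest p and the most abundant member not called. Secondary lists with at least 3 called members added up to 3, or up to 2 where the list did not pass its test. Lists of other cell types and technical lists added their 1 or 2 most abundant members. A gene that the rule selects is not reported here.

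The alternatives were other mean count minimums, adjustment over every gene, an empirical null, centring, a test against a 1.5-fold change, other thresholds, and other settings of the list test. The steps were tested on simulated data. With the standard errors of the 14063 tested genes, 27.6% of genes simulated at 1.5-fold were called, 66.6% at 2-fold, 86.0% at 3-fold and 91.4% at 4-fold, and 4.3% of calls were false. In simulated lists with no effect, 3.2% had a p under 0.05. Both simulations drew genes independently and with exactly the assumed spread. They therefore do not show the share of false calls where genes move together or the spread is wider. The statistics of the tested genes were wider than those simulated, with an empirical null standard deviation of 1.127. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.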

Results

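RNA was measured in PANC-1 pancreatic cancer cells in 2 libraries transfected with SOX9 siRNA and 2 transfected with control siRNA. The values are the authors' comparison of these groups, with a mean normalized count, a log2 fold change and its standard error per gene. Of 19830 genes, 14063 were tested, and their median mean normalized count was 1279. The median standard error of the tested genes was 0.215 on the log2 scale. The series title names cancer biomarker genes and cilia genes as the subject, and the comparison asks which genes differed after SOX9 siRNA.

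SOX9, the siRNA target, had a lower value that did not pass the adjusted threshold. In the authors' deposited table its level was 55.9% of control, with a 95% interval from 39.2% to 79.8%. The log2 fold change of SOX9 there was -0.84 with a standard error of 0.26, and the authors' deposited table gave a DESeq2 adjusted p of 0.0643. By p it ranked 289 among the tested genes. Its antisense neighbour SOX9-AS1, named after its value was seen, had a log2 fold change of 1.08 in the authors' deposited table with an adjusted p of 0.593. The direction of every fold change here was read from the sign at SOX9, so this value is no check of the labels.

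SOX9 siRNA was accompanied by 122 genes that rose and 132 that fell at an adjusted p under 0.05 in the authors' deposited table. Among called genes with a mean normalized count of at least 100, the largest rises included several cilia genes. DNAH7, an inner-arm dynein heavy chain of motile cilia, rose 6.33-fold in the authors' deposited table (95% interval 3.36 to 11.9), and C9orf116, now PIERCE1, a protein inside the axoneme's microtubules, rose 5.99-fold (3.38 to 10.6). C6orf165, now CFAP206, rose 4.50-fold, ROPN1L of the radial spokes 4.17-fold, and the tubulin-modifying enzyme family member TTLL9 4.10-fold in the authors' deposited table. ZMYND10, which helps assemble dynein arms, rose 4.05-fold, NME5 of the radial spokes 3.63-fold, and the imprinted gene RTL1 3.48-fold, per the authors' deposited table. The adjusted p of these 8 genes ranged from 1.64e-06 for C6orf165 to 0.00198 for TTLL9 in the authors' deposited table.

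The 8 largest falls at that mean count were of genes with differing roles. TINAGL1, a secreted protein of basement membranes, fell to 20.8% of control in the authors' deposited table (95% interval 12.3% to 35.3%). EPCAM, an epithelial adhesion molecule, fell to 29.5% (19.4% to 44.8%) and the centromere protein CENPM to 34.2% (23.4% to 49.9%) in the authors' deposited table. DDAH1, which breaks down methylated arginine, stood at 34.8% of control, SLC45A3 at 36.0% and the junction scaffold LIN7C at 36.1% in the authors' deposited table. TUB, a tubby protein that carries receptors into cilia, stood at 36.9% and the receptor NOTCH2 at 37.8% in the authors' deposited table. NOTCH2 may share reads with near-identical NOTCH2NL copies, which was not measured, so its value is uncertain. Adjusted p ran from 7.86e-06 for DDAH1 to 0.0123 for SLC45A3 in the authors' deposited table. By point estimate all 8 stood lower, relative to control, than SOX9, and that difference was not tested.

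**Figure D1:**
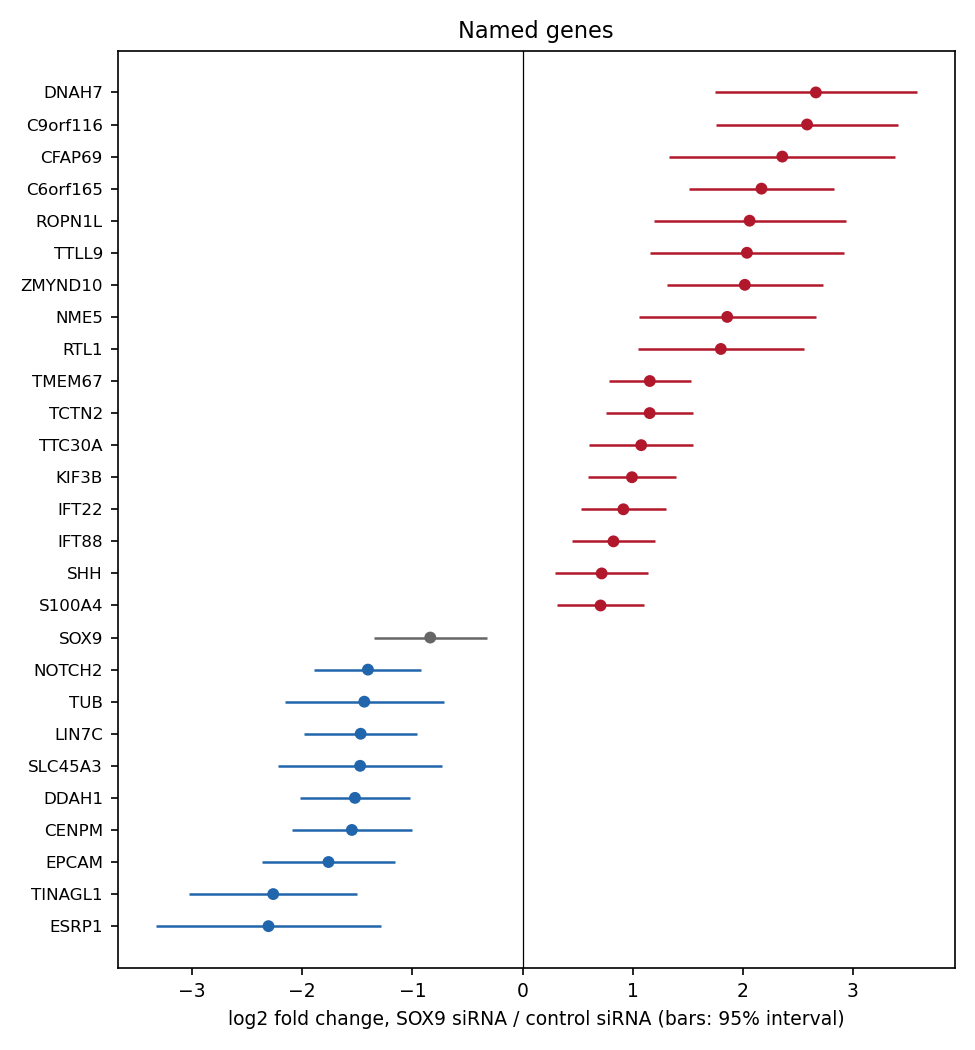
Log2 fold change of SOX9 siRNA over control siRNA (horizontal axis) for SOX9 and called genes named by the rule, with bars for the 95% interval. Genes named only as the most abundant of a list, such as CD68 and DICER1, are not drawn. Red genes rose and blue genes fell at an adjusted p under 0.05, and SOX9 in grey, at -0.84, did not pass.

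The share of rises is given by expression level as a description, without a test. The tested genes were put into 4 groups of equal size by mean count. In the group with the lowest mean counts, 30 genes rose and 5 fell, which is 85.7% rises. In the next group 47 rose and 30 fell, and in the one after it 27 rose and 31 fell. In the most abundant group 18 rose and 66 fell, which is 21.4% rises. The median log2 fold change went from 0.09 in the lowest group to -0.07 in the highest. Of all calls 48.0% were rises, and 57.0% after centring of the fold changes.

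**Figure D2:**
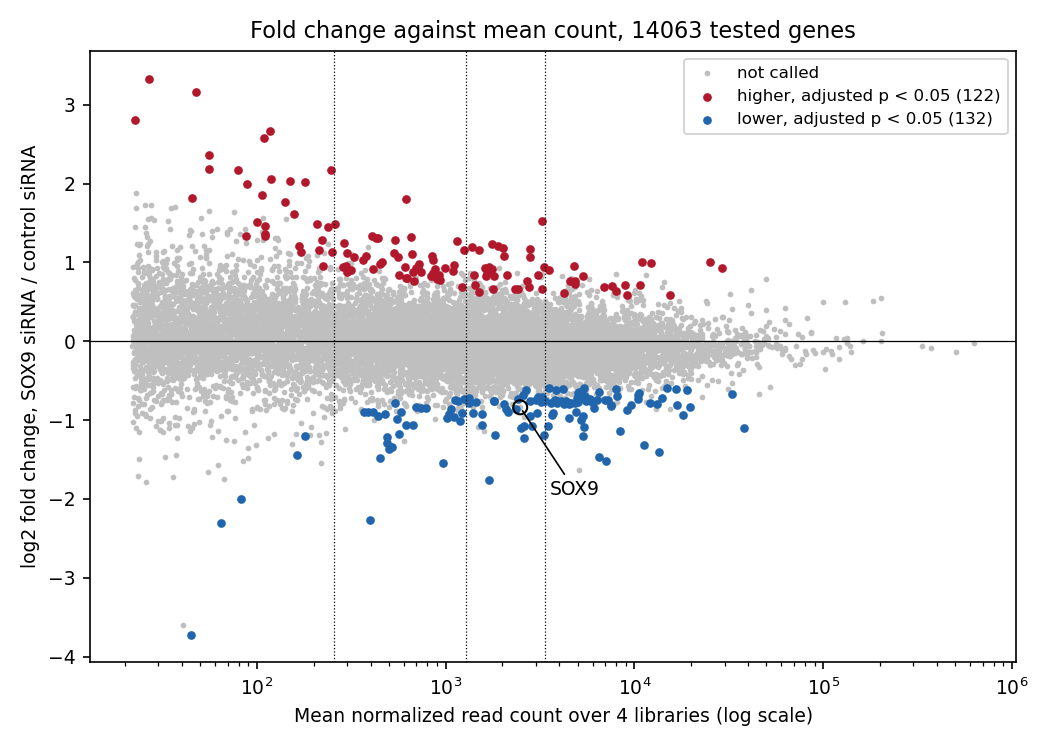
Log2 fold change of SOX9 siRNA over control siRNA (vertical axis) against the mean normalized count on a log scale, with 1 point per tested gene and dotted lines between the 4 groups of mean count. The 122 rises in red lie more to the left and the 132 falls in blue more to the right.

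Genes of cilia rose as groups. Intraflagellar transport genes, which carry cargo along the cilium, had 8 rises and 0 falls among 33 tested members, with a median log2 fold change of 0.46. Motile cilia genes had 11 rises and 0 falls among 50, with a median of 0.59. Genes of the BBSome, transition zone and ciliary membrane had 5 rises and 1 fall among 51, with a median of 0.18. Adjusted over the list alone, 14 intraflagellar transport genes rose and 1 fell, 14 motile cilia genes rose, and 9 genes of the BBSome and transition zone rose and 2 fell. The list test gave adjusted p-values of 1.34e-16, 1.28e-14 and 7.74e-05 for intraflagellar transport, motile cilia and BBSome lists. The BBSome call would end at a correlation between genes of 0.08, and its adjusted p was 0.111 at a correlation of 0.1. Fisher's exact test gave adjusted p-values of 1.11e-06, 1.89e-08 and 0.00261 in the same order. Together 24 of the genes that rose, 19.7%, belonged to these lists.

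KIF3B, a motor subunit of intraflagellar transport, rose 1.99-fold in the authors' deposited table, and the transport proteins IFT22 and IFT88 rose 1.89-fold and 1.77-fold. TTC30A rose 2.11-fold in the authors' deposited table but may share reads with its near-identical copy TTC30B, which also rose, so neither value is certain. WDR34, the most abundant transport gene that was not called, had a log2 fold change of 0.06 in the authors' deposited table. Of the transition zone genes, TMEM67 rose 2.23-fold and TCTN2 2.22-fold in the authors' deposited table, with adjusted p-values of 3.86e-06 and 1.85e-05. TUB was the member that fell, and PKD1, the most abundant member not called, had a log2 fold change of 0.14 in the authors' deposited table. Among motile cilia genes the 4 with the smallest p were DNAH7, ZMYND10, ROPN1L and CFAP69, and CFAP69 rose 5.13-fold in the authors' deposited table (95% interval 2.52 to 10.5). CFAP69 had a low mean normalized count of 56.0. DNAAF5, the most abundant motile cilia gene not called, had a log2 fold change of 0.31 in the authors' deposited table with an adjusted p of 0.449.

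The motile list had a higher median than the 84 tested genes of the intraflagellar transport and BBSome lists, 0.59 against 0.30. The difference was 0.29, with a permutation p of 0.0029. With a mean normalized count of at least 100 the difference was 0.12 and p was 0.217. An estimated correlation between genes could not be had without values per library, so the correlation that would end each call was computed. It was 0.32 for intraflagellar transport and 0.23 for motile cilia, beside the 0.08 of the BBSome list.

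**Figure D3:**
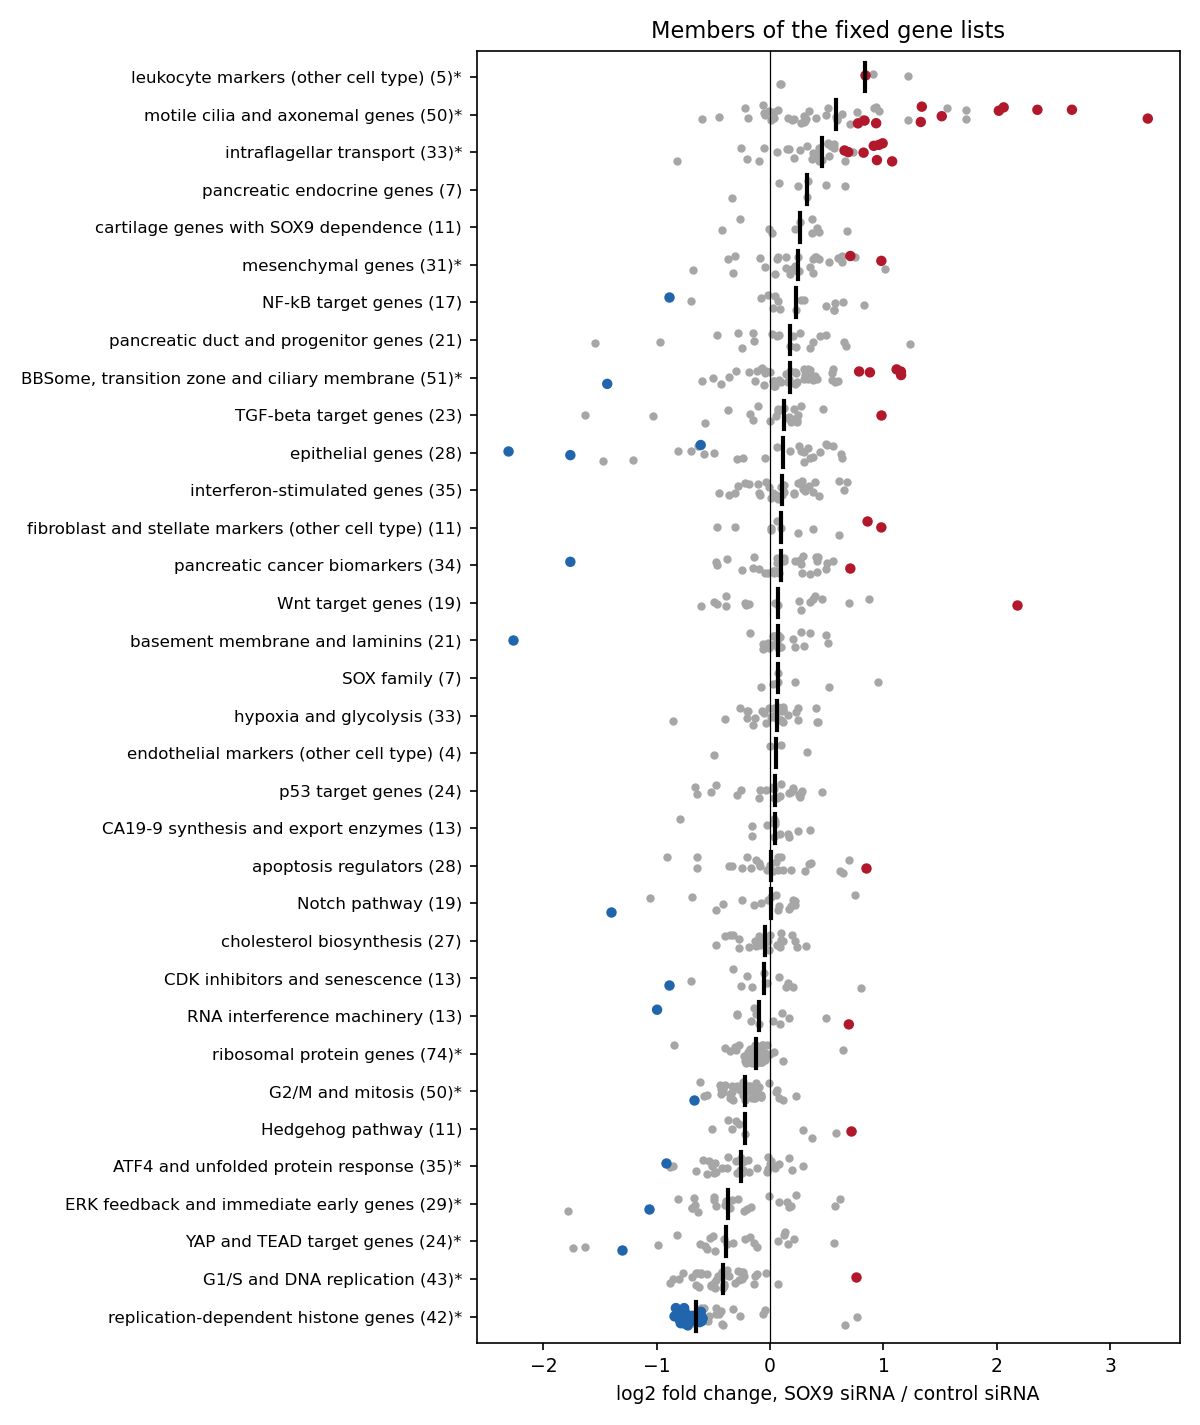
Log2 fold change of SOX9 siRNA over control siRNA (horizontal axis) of every tested member of each fixed list, with the number of tested members in parentheses, a black bar at the median and an asterisk where the list test passed. Red members rose and blue members fell at an adjusted p under 0.05. The medians ran from 0.84 for leukocyte markers to -0.65 for histone genes.

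The list of pancreatic cancer biomarkers did not pass its test. Of 34 tested members 1 rose, 1 fell and 32 were not called, and 3 passed when adjusted over the list alone, 2 of them higher. EPCAM fell to 29.5% of control, and S100A4, a calcium-binding protein of motile cells, rose 1.63-fold in the authors' deposited table (95% interval 1.24 to 2.15) with an adjusted p of 0.0363. KRT18, a keratin of simple epithelia and the most abundant biomarker not called, had a log2 fold change of 0.50 and an adjusted p of 0.106 in the authors' deposited table. The list had a median of 0.10 and an adjusted p of 0.069. It passed under 4 other settings of the list test, with an adjusted p as low as 0.0306 at a mean count of at least 100. It did not pass at a correlation of 0.05, with an adjusted p of 0.25, or when ranked by fold change, with 0.475. The enzymes of CA19-9 synthesis and export, the antigen used as a blood marker, had 0 calls among 13 tested genes and an adjusted p of 0.585.

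Duct and progenitor genes had 0 calls among 21 tested members, 0 when adjusted over the list alone, with a median of 0.18 and an adjusted p of 0.637. Their most abundant member KRT19 had a log2 fold change of 0.50 with an adjusted p of 0.259 in the authors' deposited table. The Hedgehog list had 1 rise among 11, also 1 when adjusted over the list alone. SHH, a ligand of the pathway, rose 1.64-fold in the authors' deposited table (95% interval 1.23 to 2.20). FOXL1, the most abundant Hedgehog list member not called, had a log2 fold change of 0.72 and an adjusted p of 0.377 in the authors' deposited table. The median of the Hedgehog list was -0.22, while its mean of 0.06 and its test pointed up, with an adjusted p of 0.637. Against random lists matched on mean count, a comparison added after the data were seen, its median was lower, with an adjusted p of 0.0264.

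Epithelial genes had 3 falls and 0 rises among 28 tested members. Adjusted over the list alone 5 passed, 3 lower and 2 higher. ESRP1, an epithelial splicing regulator, fell to 20.2% of control in the authors' deposited table (95% interval 9.93% to 41.1%). Its mean normalized count was low, at 64.5. PKP3, a desmosome protein named after its value was seen, fell to 65.4% in the authors' deposited table. The median of the epithelial list was 0.12, while its mean was -0.20 and its test pointed down with an adjusted p of 0.637, or 0.0288 when ranked by fold change. Mesenchymal genes rose as a list, with a median of 0.25 and an adjusted p of 0.0007, and the call would end at a correlation of 0.07. Mesenchymal genes did not pass Fisher's exact test, with an adjusted p of 0.418. Their 2 called members of 31, also 2 when adjusted over the list alone, were S100A4 and COL1A1, a collagen chain, which rose 1.97-fold in the authors' deposited table. COL1A1 was named after its value was seen.

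Histone and cell cycle genes were lower. Replication-dependent histone genes, which are expressed in S phase, had 22 falls and 0 rises among 42 tested members, with a median of -0.65. Adjusted over the list alone 35 fell. They made up 16.7% of the genes that fell, and the adjusted p was 2.83e-33 by the list test and 2.32e-26 by Fisher's exact test. HIST1H1B and HIST1H1C, the most abundant of them, fell to 56.2% and 65.0% of control in the authors' deposited table. Core histone genes may share reads between near-identical copies, which was not measured, so single values among them are uncertain.

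Genes of the G1/S transition and DNA replication fell as a list, with a median of -0.42, 41 of 43 members negative and an adjusted p of 1.05e-07. The 1 called member went the other way: GINS1, part of the replicative helicase, rose 1.69-fold in the authors' deposited table, and it was also the 1 gene adjusted over the list alone. G2/M and mitosis genes fell as a list, with a median of -0.22, 45 of 50 negative and an adjusted p of 3.46e-06. TOP2A, which untangles chromosomes, fell to 62.8% in the authors' deposited table, and 2 fell when adjusted over the list alone. The calls would end at correlations of 0.5 for histone genes, 0.13 for G1/S and 0.1 for G2/M. The G1/S and G2/M lists did not pass Fisher's exact test, with adjusted p-values of 0.865 and 0.911. Cell cycle inhibitors and senescence genes had 1 fall among 13 and an adjusted p of 0.637. Ribosomal protein genes were slightly lower, with a median of -0.12, 0 called of 74 and an adjusted p of 0.000661, which would end at a correlation of 0.05. The most abundant, RPS16 and RPLP0, had log2 fold changes of -0.23 and -0.10 in the authors' deposited table. GINS1 and TOP2A were named after their values were seen.

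Signalling and stress lists held few called genes. Genes of ERK feedback and the immediate early response fell as a list, with a median of -0.37 and an adjusted p of 8.80e-05, and YAP and TEAD targets fell with a median of -0.39 and an adjusted p of 0.000329. ATF4 and unfolded protein response genes fell with a median of -0.26 and an adjusted p of 0.00078. These 3 calls would end at correlations of 0.1, 0.09 and 0.07. Fisher's exact test did not pass for any of the 3 lists, with adjusted p-values of 0.719, 0.689 and 0.787. Their called members, named after their values were seen, were DUSP6, a phosphatase that turns off ERK, at 47.7% of control, CYR61, a secreted matricellular protein, at 40.3%, and the chaperone DNAJB9 at 52.8% in the authors' deposited table. Adjusted over the list alone, 6 ERK genes, 2 YAP genes and 4 ATF4 genes fell.

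Other lists did not pass in the main test. NF-kB targets, with a median of 0.23, passed under 5 other settings of the list test. They had 0 rises and 1 fall among 17 tested members, also 1 fall when adjusted over the list alone. Their adjusted p was as low as 0.00476 when members of other lists were left out. NF-kB targets did not pass at a correlation of 0.05, with an adjusted p of 0.16, or when ranked by fold change, with 0.145. Adjusted p-values were 0.0574 for NF-kB targets, 0.637 for Wnt targets, 0.341 for the Notch pathway, 0.674 for TGF-beta targets, 0.734 for p53 targets and 0.664 for apoptosis regulators. They were 0.341 for interferon-stimulated genes, 0.639 for cholesterol biosynthesis, 0.695 for hypoxia and glycolysis, 0.594 for basement membrane genes, 0.177 for the SOX family, 0.342 for cartilage genes and 0.127 for endocrine genes. The mean and median differed in sign for TGF-beta targets (-0.02 and 0.12), p53 targets (-0.02 and 0.05) and the Notch pathway (-0.14 and 0.01). Among single members named after their values were seen, AXIN2, a feedback inhibitor of Wnt signalling, rose 4.51-fold in the authors' deposited table, at a mean normalized count of 79.9. The chemokine CXCL1 fell to 53.8% and the apoptosome protein APAF1 rose 1.79-fold in the authors' deposited table. Adjusted over the list alone, 3 Wnt, 2 Notch, 1 NF-kB, 1 TGF-beta, 1 apoptosis, 1 basement membrane and 1 senescence list member passed, and 0 of the p53, interferon, cholesterol, hypoxia, SOX, cartilage and endocrine lists.

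Of the fixed markers of other cell types, 5 of 23 leukocyte, 4 of 17 endothelial and 11 of 19 fibroblast and stellate genes were tested. The leukocyte list rose with a median of 0.84 over 5 tested members and an adjusted p of 0.00658, which would end at a correlation of 0.1. Fisher's exact test gave this list an adjusted p of 0.381. CD68, a lysosomal protein that many cell types express, rose 1.79-fold in the authors' deposited table at a mean normalized count of 2102, while CORO1A had a log2 fold change of 0.09. Fibroblast and stellate markers had 2 rises among 11 and an adjusted p of 0.0611, or 0.0227 at a mean count of at least 50. The fibroblast list did not pass at a correlation of 0.05 (0.144), with ranks (0.161) or when ranked by fold change (0.121). It also did not pass with members of other lists left out (0.162). Of its members, CSPG4 rose 1.82-fold and FBLN1 had a log2 fold change of 0.10 in the authors' deposited table. Endothelial markers had 0 calls among 4 and an adjusted p of 0.695, with a mean of -0.02 but a median of 0.05 and a test that pointed up, and EGFL7 and ENG had log2 fold changes of 0.32 and 0.00 in the authors' deposited table. RNA interference genes had 1 rise and 1 fall among 13 and an adjusted p of 0.847. DICER1, which cuts small RNA precursors, fell to 50.1% of control, TNRC6B, named after its value was seen, rose 1.62-fold, and the exporter XPO5 had a log2 fold change of -0.10 in the authors' deposited table. Adjusted over the list alone, 1 leukocyte, 2 fibroblast, 0 endothelial, 0 ribosomal and 2 RNA interference genes passed. The acinar list had 2 tested members and the list of mitochondrially encoded genes had 0, so neither was tested as a list.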

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

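The correlation of 0.1 and the random lists matched on mean count were chosen after the data were seen. No paired analysis was possible because the table has no values per library. Other normalizations, count tests, filters on counts per library, a replicate block, a pseudocount and leaving out a library were not run for the same reason. The 254 calls became 94 with an empirical null, 109 at an adjusted p under 0.01, 93 with an absolute log2 fold change of at least 1, and 3 when tested against a 1.5-fold change. Rises were 56.4%, 55%, 64.5% and 100% of these in the same order, and 57.0% after centring, against 48.0%. SOX9, with an adjusted p of 0.0643, passed only at a threshold of 0.1, and its adjusted p ranged from 0.0571 to 1 over the alternatives. None of the named genes changed direction, but only centring altered the fold changes, and by a small fixed amount, so this is no check of direction. Of 47 called named genes, 30 still passed with the empirical null.

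All 12 lists that passed did so under every planned setting of the list test, except that 11 did at a correlation of 0.05. The number went to 4 at a correlation of 0.1, where the BBSome list had an adjusted p of 0.111 and G2/M 0.0621. By Fisher's exact test only the intraflagellar transport, BBSome, motile cilia and histone lists of these 12 passed. The others had Fisher adjusted p-values from 0.381 for leukocyte markers to 0.942 for ribosomal protein genes. Cancer biomarkers passed with a correlation of 0 (0.0329), mean counts of at least 50 (0.0478) or 100 (0.0306), ranks (0.0416) and matched random lists (0.0322). NF-kB targets passed with a correlation of 0 (0.033), mean counts of at least 50 (0.0246) or 100 (0.0229), ranks (0.0416) and members of other lists left out (0.00476). Fibroblast and stellate markers passed with a correlation of 0 (0.0428) and mean counts of at least 50 (0.0227) or 100 (0.0315), and epithelial genes were lower when ranked by fold change (0.0288). Against matched random lists the Hedgehog list was lower (0.0264). The direction of uncalled lists turned for Wnt targets (0.772) and epithelial genes (0.612) at a mean count of at least 100, epithelial genes with ranks (0.846), and p53 targets (0.919), TGF-beta targets (0.919) and endothelial markers (0.94) when ranked by fold change. The motile minus primary cilia difference was 0.117 at a mean count of at least 100, with 24 motile genes in place of 50. At these standard errors 66.6% of genes simulated at 2-fold were called, so smaller changes are often missed. Apart from fewer genes in that setting, the cause was not tested.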

Other observations

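The scan of symbol families, the run of neighbouring genes and the tests of list choice, cycling cells, histone genes and SOX9 below were chosen after the results they bear on were seen, as were the genes named here. The matched random lists were also added then, with their bounds set before their result. Symbol families, genes whose symbols share the letters before the first digit, were compared by the list test, and 10 of 344 passed. The ciliary families CFAP, IFT, DNAAF, BBS and DRC were higher, with adjusted p-values of 6.61e-08, 6.61e-08, 0.000624, 0.0234 and 0.0234. Fixed lists already held 17 of 17 IFT, 8 of 8 BBS, 6 of 9 DNAAF, 11 of 28 CFAP and 1 of 7 DRC genes, so the IFT and BBS families repeat those lists. The matrix metalloproteinase family MMP, the retrotransposon-derived RTL family and CYB genes were higher too, at 0.0234, 0.0234 and 0.0371. The small nucleolar RNA host genes SNHG and the nucleolar NOL genes were lower, both at 0.0234, with medians of -0.19 and -0.31. DPCD, a gene tied to primary ciliary dyskinesia and in no list, rose 2.29-fold in the authors' deposited table with an adjusted p of 1.64e-06.

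An imprinted cluster on chromosome 14 stood out by position. Among 13789 genes in the order of the reference gene table, the run of 5 neighbours with the highest mean Wald statistic was WDR25, BEGAIN, MEG3, RTL1 and SNHG24, at 3.69. In 1000 shuffles of the gene order 1 run was as high. MEG3, an imprinted long RNA, rose 2.89-fold in the authors' deposited table, and RTL1 rose 3.48-fold. MEG9 had a log2 fold change of 1.55 and an adjusted p of 0.0768, and BEGAIN 0.62 and 0.0723, in the authors' deposited table. Among the neighbours examined only MEG3 and RTL1 were called. DIO3OS had a log2 fold change of 0.08 and an adjusted p of 0.989 in the authors' deposited table. Genes here overlap and can be read from shared transcripts, so they are not independent, and the 4.21 reached by a shuffle shows that chance can give such a run.

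Cilia genes rose together. The tests argue against low counts. The medians of the intraflagellar transport and motile lists were compared with random lists matched on mean count. Both lay at least 0.38 above the upper end of the 95% range of those lists. With genomic span matched too the value was 0.39, which argues against genomic span. Transcript length was not matched, so an effect of it stays open. Whether the choice of list members matters stays undecided: 17 CFAP genes in no list had a median of 0.43, but that family was picked because it ranked highest in the scan and held genes already seen to rise. Fewer cycling cells stays open: 3 of the 3 cell cycle and histone lists were lower, and cells build cilia mainly outside division, so this may account for some of the rise. A direct effect of lower SOX9 also stays open, as does an effect of the siRNA on other transcripts, and neither was tested.

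Histone genes fell together. Whether a lower yield of RNAs without a poly(A) tail played a part stays undecided. Small nucleolar RNA genes had a median of -0.16 against -0.65, with bootstrap intervals over genes that did not meet. That median was itself below 0, and the intervals take genes as independent. These short RNAs also need not be recovered as histone RNAs are, so the comparison cannot decide. The H1 genes, which differ in sequence, had a median of -0.73 with 4 of 4 called, so shared reads do not account for their fall. They belong to the same list, whose fall had been seen when they were chosen. For the core histone genes shared reads therefore stay undecided. Fewer cells in S phase may explain the fall, given the adjusted p of 1.05e-07 for G1/S and DNA replication genes, but no cell cycle measurement was analysed here.

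SOX9 was lower but missed the adjusted threshold. An offset of the normalization stays undecided, since size factors hold the median log2 fold change, -0.0275 over genes with a mean count of at least 100, near 0 by construction. A wide spread at SOX9 may explain it, since its standard error lay at percentile 95.8 of the 500 genes nearest in mean count. Whether the libraries differed in knockdown could not be seen without values per library.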
